A study of Homo sapiens with 8 samples.

How the data were processed

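MDA-MB-231 cells were kept in DMEM with 10% serum and given 5 µM c-di-GMP or vehicle for 24 h, and total RNA was sequenced from 4 libraries per group. Whether the libraries of a group came from separate cultures is not stated, nor is whether the library kit kept the strand, so that genes overlapped by another on the opposite strand are uncertain. Named for the submitters' processing are CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, tools that serve for base calling, trimming, alignment, counting and testing, but only their names and versions were at hand and not how each was used. The notes name a mouse genome build, but the deposited tables hold human gene identifiers, and all 16383 have the same chromosome, start and end in GENCODE v29, on GRCh38. One deposited table gives read counts per gene and the other gives FPKM, and each lists 16383 genes, of which 14707 are in both. Both are sorted by the sum of a gene over the libraries. Genes listed with FPKM only held at most 55 counts over the 8 libraries, the lowest total in the count table. Each table thus looks like the top of a longer one, and genes detected are counted among the listed genes only.

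The authors' FPKM values could be turned back into whole reads, and the lowest total of a gene in the count table was 55 counts over the 8 libraries. The 22 gene names that a spreadsheet had turned into dates were restored from the gene identifiers. The counts were used for every test, and FPKM values for alternatives only. For all 8 libraries and for the 7 without vehicle replicate 3, genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with treatment as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are given with a standard error, and approximate 95% intervals were computed from it. Gene levels are CPM after TMM scaling, with SD. Library measures were compared by exact permutation tests, two-sided, over 70 assignments for 8 libraries and 35 for 7.

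The test with all 8 libraries was fixed before the data were examined, and it called 0 genes by edgeR, with 960 at an unadjusted p under 0.05, 106 genes by DESeq2 and 0 by limma-voom. Leaving out each library in turn was also planned then. Chosen after seeing the data were the use of the 7 libraries as a comparison of its own, the GC correction, the GC and length correction, limma-voom with library quality weights, 15 gene families and the list of aryl hydrocarbon receptor targets. In the GC correction, a lowess trend (span 0.3) of each library's deviation from the gene mean on the GC content of the longest transcript was entered as an offset. The length correction added the same kind of trend on gene length.

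The text names genes by a rule fixed before the data were examined. Among protein-coding genes past the threshold, with a mean of at least 1 CPM over all 8 libraries and groups that did not overlap, it takes the 12 largest rises and falls and the 5 smallest p each way, and of each list up to 4 members with the smallest p. It also takes PSMD3, STING, CGAS, TBK1 and IRF3, and the 10 smallest p each way if fewer than 10 genes pass, which was the case with all 8 libraries. Its first 2 parts were applied to the 7 libraries after the data were seen, and for GC-corrected fits they required the GC-corrected values of the groups not to overlap. The 35 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives. Counts of members use the adjusted p over all genes, with those adjusted over the list alone beside them.

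The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals without TMM, no filter, a stricter filter, protein-coding genes only, 3 fits on log2 FPKM, a replicate block, and each library left out. The tests were tried on simulated data with 50 changed genes at each fold. Among 7 simulated libraries with a GC trend that differed between groups, 2362 unchanged genes were called without correction and 12 with it. The added trend was made in the same way as the correction, so that its removal was fixed in advance. The 12 calls therefore do not show how well the correction removes a real bias. With all 8 libraries 1 unchanged gene was called, and with 7 libraries and no trend 7 were. Every simulated library had the same spread, which the 8 real ones did not.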

Results

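Gene expression was measured by RNA sequencing in MDA-MB-231 cells, a human breast cancer line of mesenchymal character, after 24 h with 5 µM c-di-GMP or with phosphate-buffered saline as the vehicle. c-di-GMP is a cyclic dinucleotide that bacteria use as a second messenger, and in mammalian cells it is bound by STING, an adaptor of innate immune signalling. The series title names metastasis, STING and PSMD3, a subunit of the 19S regulatory particle of the proteasome. There were 4 libraries of vehicle-treated cells and 4 libraries of c-di-GMP-treated cells. The deposited count table lists 16383 genes, and the libraries held between 16151360 and 18040010 counts, so that 3 counts corresponded to 0.166 to 0.186 CPM (counts scaled to library size), a floor that covers counting error only. Totals, in units of 1e+06 counts, were 17.5 ± 0.518 (SD, n = 4) with vehicle and 17.2 ± 0.699 (SD, n = 4) with c-di-GMP, a difference within the spread between libraries (exact permutation test, two-sided, p = 0.486). The labels do not say whether the libraries of a group came from separate cultures, so that the p-values measure only the spread between these libraries, which may be technical.

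Vehicle replicate 3 stood apart from the other 7 libraries. Its log2 CPM values correlated with those of the others across genes, which are not independent replicates, at 0.862 to 0.878, while the 21 pairs among the other 7 libraries correlated at 0.988 to 0.994. Genes of at most 2541 bases took 28.4% of its counts, against 13.8% to 15.6% elsewhere, and genes of at least 6964 bases took 18.97%, against 34.6% to 36.5%. Transcripts encoded in mitochondria made up 1.40% of its counts, against 3.58% to 5.00%, and processed pseudogenes 0.883%, against 0.291% to 0.322%. In it 465 of the 16383 listed genes had no count, against 2 to 9 genes in the other libraries. Its deposited counts summed to 145.6% of the denominator of its deposited FPKM values, against 92.4% to 94.4%. Single genes differed as well: TBK1, a kinase that acts downstream of STING, stood at 12.87 CPM there and at 27.93 to 29.28 CPM in the other vehicle libraries, and the transcription factor IRF3 at 210.45 CPM, against 59.02 to 65.26 CPM. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 1.76), so that each was counted as 1 sample. This does not show that they came from separate cultures. By the same measure vehicle replicates 1 and 2 stood at 7.56, and vehicle replicate 2 stood at 6.10 to 7.50 from the c-di-GMP libraries. Vehicle replicate 4 stood at 4.67 and 2.78 from replicates 1 and 2. The c-di-GMP libraries stood at 19.66 to 22.58 from vehicle replicate 1 and at 9.46 to 11.07 from replicate 4.

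**Figure D1:**
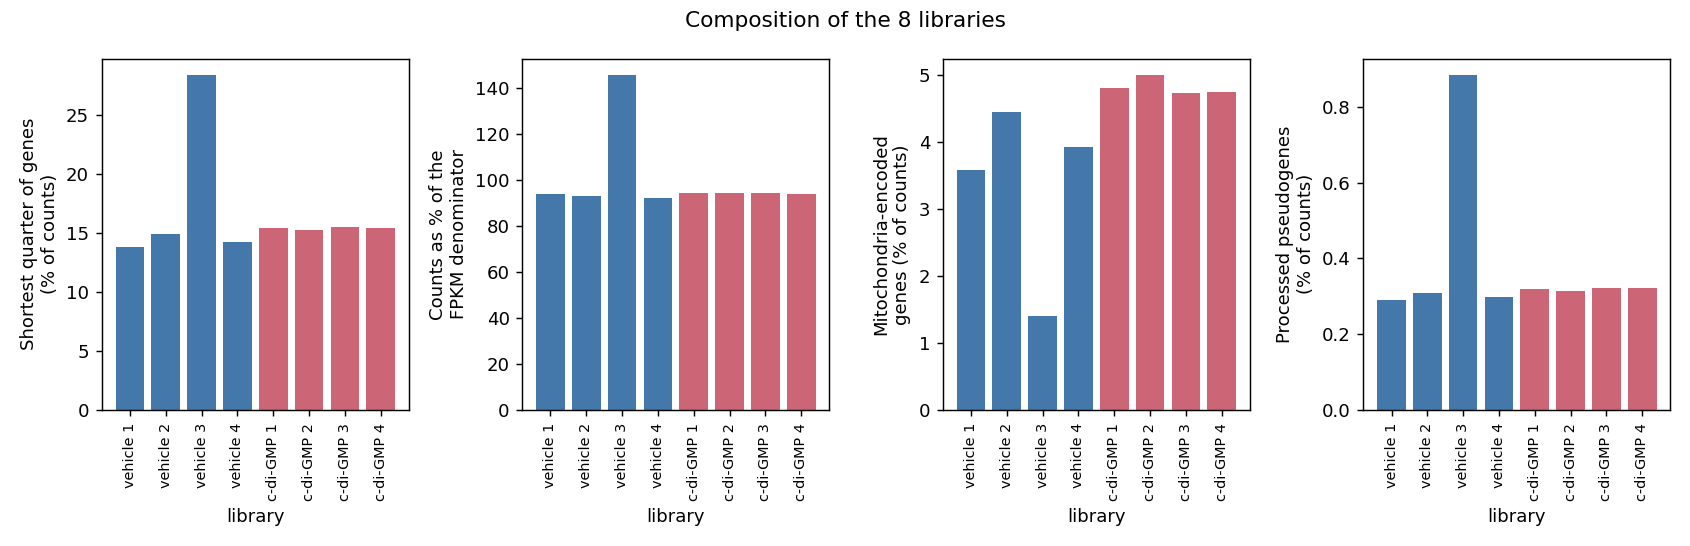
Bars give, for each of the 8 libraries (blue, vehicle; red, c-di-GMP), the percent of counts from genes of at most 2541 bases, the counts as a percent of the FPKM denominator, and the percent of counts from mitochondria-encoded genes and from processed pseudogenes. Vehicle replicate 3 lies outside the range of the other 7 libraries in all 4 panels.

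The first comparison asked which transcripts differed after 24 h of c-di-GMP when all 8 libraries were used, and no gene passed the threshold. Among the genes with the smallest p on the higher side, the fatty acid desaturase SCD had a log2 fold change of 0.45 ± 0.11 (SE) and the acyl-CoA ligase ACSL3 one of 0.32 ± 0.09. On the lower side, F2RL3, which encodes a thrombin receptor, had a log2 fold change of -1.61 ± 0.26, the transcription factor FOXQ1 had -0.61 ± 0.10, and ASB2, a substrate receptor of ubiquitin ligases, had -1.42 ± 0.27. The others among the 10 smallest p values in each direction were PTGFR, PDE1C, SPDYA, EVI2B, TSACC, MIR570, OLA1 and TMEM267 on the higher side and CEBPB, SCNN1D, FAM171A2, C8orf82, ZNF579, LTBP3 and ARVCF on the lower side. All of them failed the correction (edgeR adjusted p = 0.623 for each). By edgeR's quasi-likelihood test 0 of 15415 genes were called, and 960 had an unadjusted p under 0.05. DESeq2 called 106 genes (28 higher, 78 lower), and limma-voom called 0, with 837 at an unadjusted p under 0.05. The biological coefficient of variation was 36.3%, and in data simulated with that spread in every library 0% of 2-fold and 56.0% of 4-fold changes were recovered. In the real data the coefficient was 4.52% without vehicle replicate 3. The spread was thus not shared evenly, and these rates need not hold for the real libraries. Without vehicle replicate 3 the same test called 4633 genes, whereas leaving out any other single library gave 0.

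The comparison without vehicle replicate 3 set 3 vehicle libraries against 4 c-di-GMP libraries. It was among the settings listed before the data were examined, but its use as a basis for describing genes, and the GC correction below, were chosen after seeing the data. Most changes were small: of 15647 genes tested, 2106 rose and 2527 fell with c-di-GMP, 56 of them by at least 2-fold, and 93.7% of the calls were changes of less than 1.5-fold. The biological coefficient of variation was 4.52%, and in simulated data 68.0% of 1.3-fold and 94.0% of 2-fold changes were recovered. Fold changes followed the GC content of the transcripts, with a median log2 fold change of 0.15 for genes of 30 to 35% GC and of -0.47 for genes of 70 to 75% GC (Spearman rho = -0.589 across genes). When each library's own GC trend was taken out, 1342 genes rose and 1036 fell, 31 of the 2378 by at least 2-fold, and 1547 of the 1585 genes called both with and without this correction had the same direction in both. Over all 8 libraries, 1044 of the 2101 rises tested there had a log2 fold change of the opposite sign, and 448 of the 2511 falls, so that the direction of many calls rests on leaving out vehicle replicate 3. The same holds for 45 of 80 rises and 12 of 99 falls among the genes that the naming rule takes, such as HSPE1 at -1.99 ± 1.03, PSMA4 at -1.39 ± 0.83 and VIM at -0.44 ± 0.45. The GC-corrected count was 1476 without vehicle replicate 1 and 1552 without vehicle replicate 4. Values with the GC trend taken out are given as GC-corrected beside the uncorrected ones, and adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

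**Figure D2:**
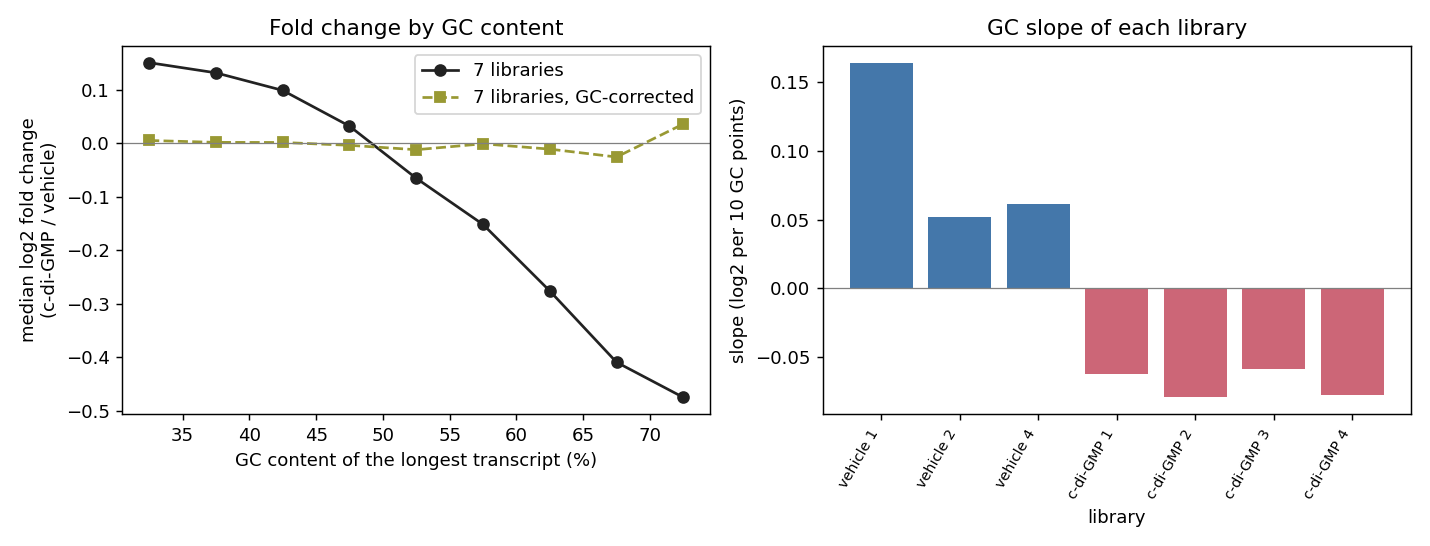
On the left, the median log2 fold change (c-di-GMP over vehicle) of genes in bins of 5 GC points is drawn against the GC content of the longest transcript, for the 7 libraries without vehicle replicate 3, before (circles) and after (squares) GC correction. On the right, bars give the slope of each library's log2 level on GC content per 10 points, from 0.05 to 0.16 in the vehicle libraries (blue) and from -0.08 to -0.06 in the c-di-GMP libraries (red).

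PSMD3 and STING, both named in the title, had RNA levels that did not differ beyond the spread between libraries. PSMD3 (ENSG00000108344, GRCh38 chromosome 17, 39980797 to 39997960) was measured at 234 ± 8.73 CPM (SD, n = 3) with vehicle and 232 ± 3.46 CPM (SD, n = 4) with c-di-GMP. Its log2 fold change was -0.01 ± 0.04 (SE), with an approximate 95% interval from -0.09 to 0.07, and 0.05 ± 0.03 GC-corrected (edgeR adjusted p = 0.826 and 0.374). STING, listed under its older name TMEM173 (ENSG00000184584, chromosome 5, 139475534 to 139482935), was measured at 35.3 ± 3.68 CPM (SD, n = 3) and 34.1 ± 1.03 CPM (SD, n = 4). Its log2 fold change was -0.05 ± 0.07, with an interval from -0.18 to 0.08, and 0.09 ± 0.06 GC-corrected (edgeR adjusted p = 0.619 and 0.354). Over all 8 libraries the log2 fold changes of PSMD3 and TMEM173 were 0.09 ± 0.13 and 0.08 ± 0.16, opposite in sign to the uncorrected values of the 7 libraries (edgeR adjusted p = 0.800 and 0.855). By library, PSMD3 stood at 245, 229.6 and 229 CPM in vehicle replicates 1, 2 and 4 and at 236, 232, 233 and 227 CPM with c-di-GMP, and at 163 CPM in vehicle replicate 3 on the scale of all 8. TMEM173 stood at 39.5, 33.2 and 33.1 CPM in the same vehicle libraries, at 33.6, 35.6, 33.8 and 33.4 CPM with c-di-GMP, and at 22.2 CPM in vehicle replicate 3.

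Other genes of cyclic dinucleotide sensing moved in different directions in the 7 libraries. TBK1 rose by 0.29 ± 0.06 (0.16 ± 0.06 GC-corrected) on the log2 scale (edgeR adjusted p = 9.53e-04 and 0.0461). SLC19A1, a folate carrier that also imports cyclic dinucleotides, rose from 1.78 ± 0.464 CPM (SD, n = 3) to 2.83 ± 0.340 CPM (SD, n = 4), a log2 fold change of 0.67 ± 0.21 (0.99 ± 0.21 GC-corrected). IRF3 fell by 0.15 ± 0.05 and stood at 0.04 ± 0.04 GC-corrected, and CGAS, the cytosolic DNA sensor, had -0.11 ± 0.06 and fell by 0.19 ± 0.05 only with the correction. The dNTP hydrolase SAMHD1 rose by 0.18 ± 0.05 and LRRC8A, a channel subunit, fell by 0.14 ± 0.04, at 0.10 ± 0.04 and 0.01 ± 0.03 GC-corrected. Of the 17 tested members of the list of sensing and transport genes, 3 rose and 3 fell, against 4 and 3 adjusted over the list alone (GC-corrected, 2 rose and 1 fell, the same counts adjusted over the list alone). The list did not pass camera's test of a set against the other genes (adjusted p = 0.646, and 0.344 GC-corrected).

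Of the interferon-stimulated genes, 3 that encode antiviral RNA-binding proteins of the IFIT family rose. IFIT3 rose from 145 ± 8.83 CPM (SD, n = 3) to 189 ± 6.83 CPM (SD, n = 4), a log2 fold change of 0.38 ± 0.05 (0.30 ± 0.04 GC-corrected), IFIT1 rose by 0.33 ± 0.05 (0.23 ± 0.04 GC-corrected) and IFIT2 by 0.27 ± 0.05 (0.17 ± 0.04 GC-corrected). Of 32 tested members, 9 rose and 1 fell, the same counts adjusted over the list alone. After GC correction 7 rose and 2 fell, against 10 and 2 adjusted over the list alone. The member that fell before correction was IRF7, a transcription factor of the interferon response, at -0.48 ± 0.08 and -0.08 ± 0.08 GC-corrected. The list passed camera's test with the preset correlation (adjusted p = 0.0158). It had adjusted p = 0.235 with an estimated correlation and 0.230 GC-corrected. Across all 8 libraries it missed the threshold (adjusted p = 0.144), with a median log2 fold change of 0.07 and a mean of the opposite sign, -0.11.

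Proteasome genes rose more often than they fell among the 7 libraries. In the 19S regulatory particle, of 19 members 9 rose and 1 fell, the same counts adjusted over the list alone, and of the 22 genes of the 20S core and its activators 11 rose and 1 fell, the same counts adjusted over the list alone. GC-corrected, 6 and 5 rose and 0 fell in each, against 9 and 9 higher adjusted over the list alone. With a length trend taken out as well, 2 and 4 rose and 0 and 3 fell, and the median of the 20S list turned to -0.0071. The core subunit PSMA4 rose by 0.33 ± 0.05 (0.23 ± 0.05 GC-corrected) and the activator PSME3 by 0.21 ± 0.04 (0.20 ± 0.03 GC-corrected), whereas the ubiquitin receptor ADRM1 fell by 0.20 ± 0.05 before correction and rose by 0.12 ± 0.04 after it. Both lists passed camera's test (adjusted p = 0.00404 and 0.00575). They had adjusted p = 0.455 and 0.464 with an estimated correlation and 0.255 and 0.291 GC-corrected. In all 8 libraries the list medians were -0.09 and -1.06, of the opposite sign, though that of the 19S list turned without TMM scaling, and vehicle replicate 3 was the library with more counts from short genes. Among 18 ubiquitin and deubiquitinase genes 7 rose and 4 fell, the same counts adjusted over the list alone (GC-corrected, 3 rose and 1 fell, against 4 and 2 adjusted over the list alone). Camera's test gave adjusted p = 0.394, and 0.987 GC-corrected, past the threshold neither time. The ubiquitin-conjugating enzyme UBE2N rose by 0.22 ± 0.04 (0.11 ± 0.03 GC-corrected), and NFE2L1, a transcription factor of proteasome genes, fell by 0.21 ± 0.04 and by 0.11 ± 0.03 GC-corrected. Of 14 heat shock genes 6 rose and 5 fell, against 7 and 5 adjusted over the list alone (GC-corrected, 6 rose and 0 fell, against 6 and 2 adjusted over the list alone). This list did not pass camera's test (adjusted p = 0.238, and 0.139 GC-corrected). Its members HSPD1 and HSPE1, which are chaperonins of mitochondria, rose by 0.25 ± 0.04 (0.17 ± 0.03 GC-corrected) and 0.39 ± 0.07 (0.41 ± 0.06 GC-corrected). Of 16 genes of endoplasmic reticulum stress 3 rose and 1 fell, against 2 and 0 adjusted over the list alone (GC-corrected, 2 rose and 1 fell, the same counts adjusted over the list alone). As a set they missed the threshold (camera adjusted p = 0.875, and 0.775 GC-corrected). Its member SEC61B, a translocon subunit, rose by 0.25 ± 0.05 (0.24 ± 0.05 GC-corrected).

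The protein-coding gene with the largest fall, among those with a mean of at least 1 CPM over all 8 libraries whose groups did not overlap, was CYP1A1. CYP1A1 (chromosome 15, 74719542 to 74725610), a cytochrome P450 induced by ligands of the aryl hydrocarbon receptor, fell from 5.00 ± 0.264 CPM (SD, n = 3) to 1.23 ± 0.514 CPM (SD, n = 4), by 2.01 ± 0.21 and by 1.94 ± 0.21 GC-corrected on the log2 scale (edgeR adjusted p = 2.70e-07 and 7.65e-07). Its relative CYP1B1 (chromosome 2, 38066973 to 38109902) fell from 151 ± 3.07 CPM (SD, n = 3) to 99.2 ± 4.39 CPM (SD, n = 4), by 0.61 ± 0.04 and by 0.69 ± 0.04 GC-corrected. With all 8 libraries their log2 fold changes were -1.79 ± 0.39 and -0.39 ± 0.25 and missed the threshold. F2RL3 fell by 1.72 ± 0.27 and by 1.48 ± 0.27 GC-corrected, ASB2 by 1.10 ± 0.11 and by 0.92 ± 0.10 GC-corrected, VIPR1, a receptor of vasoactive intestinal peptide, by 0.91 ± 0.07 and by 0.83 ± 0.07 GC-corrected, and the cytokine gene IL24 by 0.87 ± 0.11 and by 0.90 ± 0.11 GC-corrected. MARCKS, a membrane protein that binds actin, fell by 0.41 ± 0.04 and by 0.49 ± 0.04 GC-corrected, and the sugar phosphate transporter gene SLC37A2 by 0.56 ± 0.05 and by 0.47 ± 0.04 GC-corrected. Further falls of 0.73 to 1.27 on the log2 scale were those of NRTN, EVA1B, KNDC1, CYGB, PDXP, ZNF467 and TNRC18, each smaller after GC correction, and MGAT2, FAM78A, LY6K and EMX1 fell as well. ACTL10 fell by 0.91 ± 0.30 and missed the threshold GC-corrected. The falls of SERF1B, by 1.70 ± 0.27 and by 1.70 ± 0.27 GC-corrected, and of GCOM1, by 0.68 ± 0.26 and by 0.78 ± 0.25 GC-corrected, are uncertain, because reads of these genes can be shared with a near-identical copy or an overlapping gene.

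Among the genes with the largest rises, many had low levels. TMA7, a short gene whose product is linked to translation, rose from 19.1 ± 0.806 CPM (SD, n = 3) to 31.9 ± 2.00 CPM (SD, n = 4), by 0.74 ± 0.07 (0.84 ± 0.07 GC-corrected), and NEDD8, the ubiquitin-like modifier of cullins, rose by 0.51 ± 0.06 (0.42 ± 0.06 GC-corrected). Over all 8 libraries both had the opposite sign (-1.99 ± 1.12 and -1.45 ± 0.90). TFF1, a secreted trefoil protein, rose from 0.544 ± 0.106 CPM (SD, n = 3) to 1.16 ± 0.364 CPM (SD, n = 4), the metallothionein MT1F rose by 0.68 ± 0.24 (0.85 ± 0.24 GC-corrected), RANGRF by 0.63 ± 0.22 (0.74 ± 0.21 GC-corrected) and RCBTB2 by 0.61 ± 0.16 (0.54 ± 0.16 GC-corrected). MYB, ARHGAP28, TSACC, DIO2, SLCO2A1 and CCDC169 also rose and missed the threshold GC-corrected. After the correction the smallest p values on the higher side included those of PFN1, an actin-binding protein, at 0.45 ± 0.04 (0.28 ± 0.05 before), the spermidine synthase SRM, at 0.37 ± 0.04 (0.07 ± 0.04 before, not past the threshold) and FAU, a ribosomal protein fusion gene, at 0.35 ± 0.04 (0.29 ± 0.04 before). C4orf48, BLOC1S1, PRR22, INKA1 and EMILIN1 were the other large rises after correction, and the last 3 of these missed the threshold without it. The GC-corrected rises of MRPL23 (0.83 ± 0.21) and F8A1 (0.72 ± 0.12) are uncertain, because near-identical copies can share their reads. The uncorrected levels of the groups overlapped for both and for SRM, C4orf48, BLOC1S1, PRR22 and EMILIN1. MRPL23 stood at 16.81, 10.22 and 9.33 CPM with vehicle and at 25.36, 11.33, 25.41 and 11.09 CPM with c-di-GMP. TFF1, MYB, INKA1 and ACTL10 had a mean under 1 CPM among the 7 libraries and met that bound only through vehicle replicate 3, where they stood at 3.22, 4.2, 6.08 and 3.58 CPM.

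**Figure D3:**
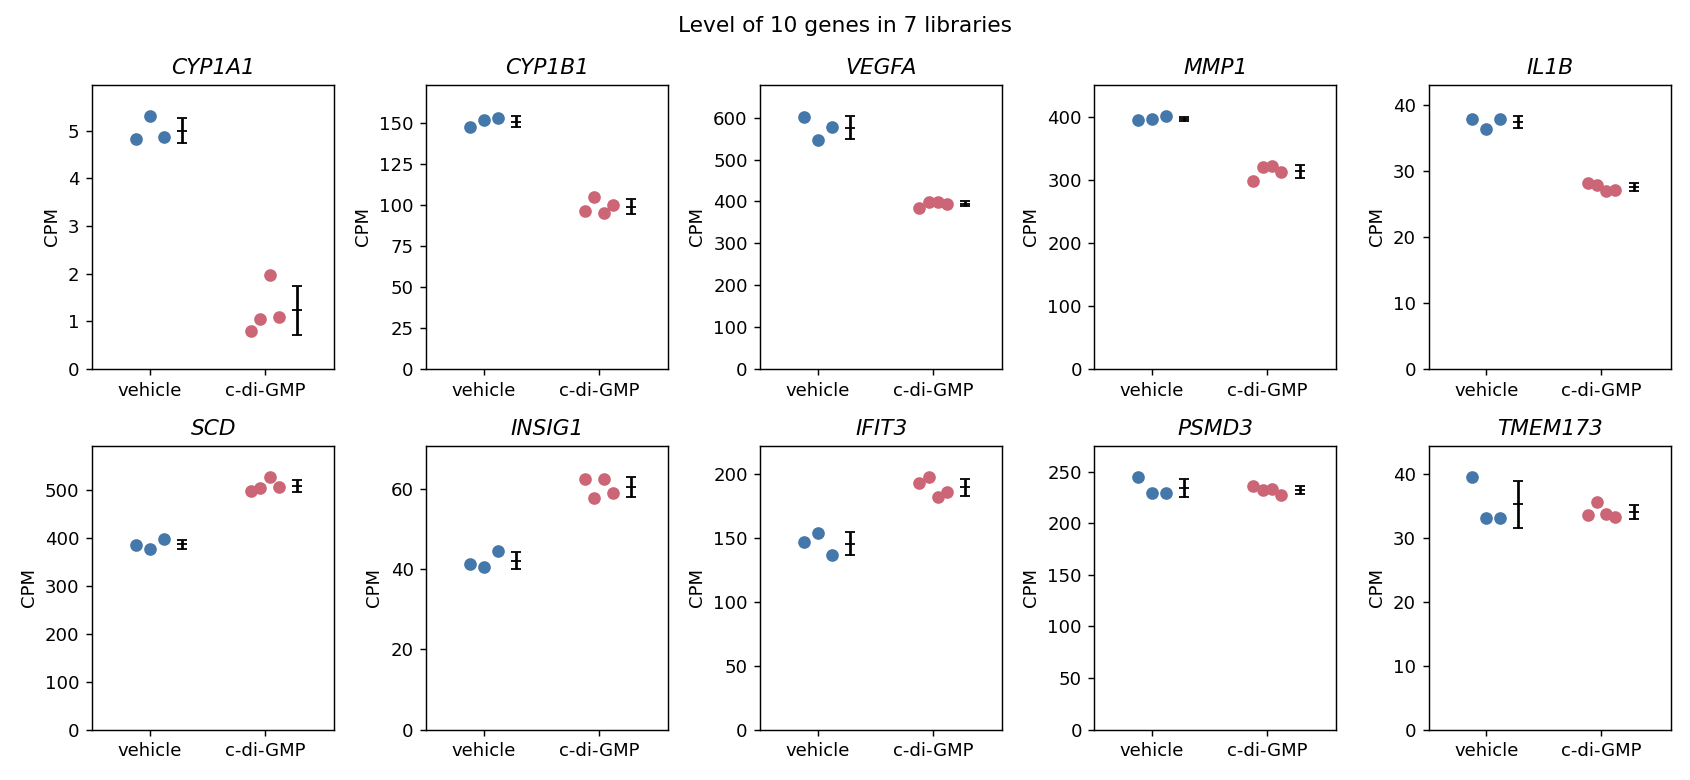
Points give the level (CPM) of 10 genes in each of the 7 libraries without vehicle replicate 3 (3 vehicle, blue; 4 c-di-GMP, red), with the mean and SD as a bar beside them. CYP1A1, CYP1B1, VEGFA, MMP1 and IL1B lie lower in each c-di-GMP library, SCD, INSIG1 and IFIT3 lie higher, and PSMD3 and TMEM173 (STING) overlap between the groups.

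Genes of invasion and matrix fell more often than they rose. MMP1 (chromosome 11, 102789920 to 102798160), an interstitial collagenase, fell from 397 ± 3.21 CPM (SD, n = 3) to 313 ± 10.9 CPM (SD, n = 4), by 0.34 ± 0.04 and by 0.43 ± 0.03 GC-corrected (edgeR adjusted p = 1.36e-06 and 3.48e-09). The membrane-bound protease MMP14 fell by 0.42 ± 0.04 and by 0.24 ± 0.03 GC-corrected and the plasminogen activator PLAT by 0.33 ± 0.04 and by 0.39 ± 0.04 GC-corrected. Of 21 secreted proteases and their inhibitors 1 rose and 5 fell, the same counts adjusted over the list alone. After GC correction 3 rose and 4 fell, the same counts adjusted over the list alone. Neither before nor after GC correction did the set pass (camera adjusted p = 0.238 and 0.987). Of 16 collagen and matrix genes 1 rose and 9 fell, against 1 and 10 adjusted over the list alone, and COL13A1 fell by 0.48 ± 0.05 and by 0.29 ± 0.03 GC-corrected and COL5A1 by 0.54 ± 0.06 and by 0.32 ± 0.04 GC-corrected. Of 25 integrin and focal adhesion genes 1 rose and 13 fell, the same counts adjusted over the list alone, and the laminin chain LAMA5 fell by 0.60 ± 0.05 and by 0.22 ± 0.04 GC-corrected and the integrin ITGB4 by 0.42 ± 0.05 and by 0.11 ± 0.03 GC-corrected. The last 2 lists passed camera's test (adjusted p = 0.00160 and 0.0125). The same 2 lists had adjusted p = 0.455 and 0.455 with an estimated correlation and 0.987 and 0.987 GC-corrected, where 1 rose in each and 6 and 7 fell. Across all 8 libraries their medians were 0.04 and 0.08, of the opposite sign.

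Lists named for migration and metastasis held members that moved both ways. Of 26 migration and cytoskeleton genes 5 rose and 7 fell, the same counts adjusted over the list alone (GC-corrected, 6 rose and 5 fell, against 7 and 7 adjusted over the list alone), and the small GTPases RHOA and RAC1 rose by 0.21 ± 0.04 (0.18 ± 0.03 GC-corrected) and 0.23 ± 0.04 (0.16 ± 0.03 GC-corrected) and the myosin MYH9 fell by 0.39 ± 0.05 and by 0.21 ± 0.04 GC-corrected. Camera's test gave adjusted p = 0.875, and 0.783 GC-corrected, past the threshold neither time. Among 21 breast cancer metastasis genes 3 rose and 7 fell, the same counts adjusted over the list alone (GC-corrected, 3 rose and 6 fell, against 4 and 7 adjusted over the list alone). This list did not pass camera's test (adjusted p = 0.238, and 0.701 GC-corrected). With GC and length trends taken out 0 of its members rose and 8 fell, and it did not pass either (camera adjusted p = 0.348). The cytokine IL11 fell by 0.43 ± 0.05 and by 0.32 ± 0.04 GC-corrected, and the actin-bundling gene FSCN1 fell by 0.40 ± 0.05 before correction and stood at -0.05 ± 0.04 after it. Of 15 metastasis suppressors 2 rose and 4 fell, against 2 and 6 adjusted over the list alone (GC-corrected, 4 rose and 5 fell, against 4 and 6 adjusted over the list alone), and NME1, a nucleoside diphosphate kinase, rose by 0.40 ± 0.07 (0.38 ± 0.06 GC-corrected) and the tetraspanin CD82 fell by 0.38 ± 0.04 and by 0.20 ± 0.03 GC-corrected. As a set they missed the threshold (camera adjusted p = 0.277, and 0.783 GC-corrected). Among 20 mesenchymal genes and transcription factors of epithelial-mesenchymal transition 5 rose and 3 fell, against 5 and 4 adjusted over the list alone (GC-corrected, 3 rose and 5 fell, against 3 and 7 adjusted over the list alone). Neither before nor after GC correction did the set pass (camera adjusted p = 0.766 and 0.344). VIM, an intermediate filament gene, rose from 659 ± 14.2 CPM (SD, n = 3) to 792 ± 25.2 CPM (SD, n = 4), and the integrin ITGA5 fell by 0.27 ± 0.04 and by 0.18 ± 0.03 GC-corrected. In the epithelial list, of 17 genes 1 rose and 7 fell, against 1 and 8 adjusted over the list alone (camera adjusted p = 0.121), and the claudin CLDN7 fell by 0.43 ± 0.06 and by 0.23 ± 0.06 GC-corrected. GC-corrected, that list passed on the higher side (adjusted p = 0.0363, and adjusted p = 0.703 with an estimated correlation), where 2 rose and 1 fell, against 4 and 1 adjusted over the list alone, and the keratin KRT7 turned from -0.16 ± 0.04 to 0.13 ± 0.03, past the threshold both times.

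VEGFA (chromosome 6, 43770184 to 43786487), an angiogenic growth factor, fell from 576 ± 27.2 CPM (SD, n = 3) to 394 ± 6.26 CPM (SD, n = 4), by 0.55 ± 0.04 and by 0.45 ± 0.03 GC-corrected (edgeR adjusted p = 4.38e-09 and 4.67e-10). In its list of hypoxia and glycolysis genes, of 25 members 3 rose and 7 fell, the same counts adjusted over the list alone (GC-corrected, 4 rose and 6 fell, against 4 and 7 adjusted over the list alone). Camera's test gave adjusted p = 0.223, and 0.987 GC-corrected, past the threshold neither time. The lactate dehydrogenase LDHA rose by 0.19 ± 0.04 (0.11 ± 0.03 GC-corrected). In the ATF4 amino acid response, of 21 genes 0 rose and 13 fell, against 0 and 14 adjusted over the list alone. After GC correction 1 rose and 9 fell, against 1 and 10 adjusted over the list alone. CEBPB fell by 0.82 ± 0.07 and by 0.44 ± 0.05 GC-corrected, the mTORC1 inhibitor DDIT4 by 0.53 ± 0.05 and by 0.37 ± 0.04 GC-corrected and the amino acid transporter SLC7A5 by 0.48 ± 0.05 and by 0.24 ± 0.04 GC-corrected. This list passed camera's test in all 8 libraries and in 7 (adjusted p = 9.94e-05 and 5.56e-05). It had adjusted p = 0.0882 and 0.235 with an estimated correlation and missed the threshold GC-corrected (adjusted p = 0.292).

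Of 19 serum-response and immediate early genes 0 rose and 10 fell, against 0 and 11 adjusted over the list alone. JUND, a subunit of AP-1, fell by 0.84 ± 0.06 and by 0.36 ± 0.03 GC-corrected, and the phosphatase DUSP4 by 0.32 ± 0.04 and by 0.28 ± 0.03 GC-corrected. The list passed in 7 libraries (camera adjusted p = 6.56e-04, and adjusted p = 0.395 with an estimated correlation) and missed the threshold GC-corrected (adjusted p = 0.987), where 0 rose and 5 fell, against 0 and 6 adjusted over the list alone. Among 24 NF-kB target cytokines and regulators 1 rose and 11 fell, against 2 and 12 adjusted over the list alone. After GC correction 1 rose and 9 fell, against 1 and 10 adjusted over the list alone. The interleukin IL1B (chromosome 2, 112829751 to 112836903) fell from 37.4 ± 0.894 CPM (SD, n = 3) to 27.6 ± 0.608 CPM (SD, n = 4), by 0.44 ± 0.06 and by 0.50 ± 0.05 GC-corrected, and the survival gene IER3 fell by 0.40 ± 0.05 and by 0.22 ± 0.03 GC-corrected. The NF-kB list passed in all 8 libraries and in 7 (camera adjusted p = 0.0233 and 0.0158). This list had adjusted p = 0.286 and 0.455 with an estimated correlation and missed the threshold GC-corrected (adjusted p = 0.344). Of 17 TGF-beta and SMAD targets 2 rose and 8 fell, against 3 and 8 adjusted over the list alone (GC-corrected, 1 rose and 5 fell, against 2 and 6 adjusted over the list alone), and SMAD7, an inhibitor of the pathway, fell by 0.52 ± 0.09 and by 0.34 ± 0.09 GC-corrected (camera adjusted p = 0.0395, adjusted p = 0.464 with an estimated correlation, and 0.987 GC-corrected). Of 15 NRF2 antioxidant genes 2 rose and 7 fell, the same counts adjusted over the list alone (GC-corrected, 2 rose and 5 fell, against 2 and 6 adjusted over the list alone). As a set these missed the threshold (camera adjusted p = 0.0554, and 0.291 GC-corrected). With GC and length trends taken out the NRF2 list just passed, with 0 rises and 7 falls (camera adjusted p = 0.0482, and 0.292 with an estimated correlation). The iron storage gene FTH1 fell by 0.37 ± 0.04 and by 0.36 ± 0.03 GC-corrected and HMOX1, haem oxygenase, by 0.44 ± 0.10 and by 0.28 ± 0.09 GC-corrected, whereas the thioredoxin TXN rose by 0.22 ± 0.05 (0.13 ± 0.04 GC-corrected). Of 17 p53 targets 2 rose and 6 fell, the same counts adjusted over the list alone (GC-corrected, 1 rose and 0 fell, the same counts adjusted over the list alone). As a set they missed the threshold (camera adjusted p = 0.238, and 0.858 GC-corrected). The cell cycle inhibitor CDKN1A fell by 0.20 ± 0.05 before correction and stood at -0.04 ± 0.03 after it. Of 16 YAP and TAZ targets 3 rose and 6 fell, against 4 and 6 adjusted over the list alone (GC-corrected, 1 rose and 3 fell, against 1 and 4 adjusted over the list alone). Neither before nor after GC correction did the set pass (camera adjusted p = 0.308 and 0.783). AMOTL2, a scaffold that binds YAP, fell by 0.28 ± 0.05 and by 0.14 ± 0.04 GC-corrected.

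Lipid synthesis genes rose more often than they fell among the 7 libraries. Of 24 cholesterol synthesis genes 10 rose and 2 fell, the same counts adjusted over the list alone. After GC correction 9 rose and 0 fell, against 14 and 0 adjusted over the list alone. INSIG1 (chromosome 7, 155297776 to 155310235), which holds the sterol sensor in the endoplasmic reticulum, rose from 42.1 ± 2.11 CPM (SD, n = 3) to 60.6 ± 2.43 CPM (SD, n = 4), by 0.52 ± 0.06 (0.47 ± 0.05 GC-corrected), with edgeR adjusted p = 3.63e-07 and 7.87e-07. IDI1 and FDFT1, enzymes of sterol synthesis, rose by 0.50 ± 0.06 (0.39 ± 0.05 GC-corrected) and 0.27 ± 0.05 (0.25 ± 0.04 GC-corrected), and the sterol carrier STARD4 by 0.34 ± 0.06 (0.19 ± 0.05 GC-corrected). The list passed camera's test with and without GC correction (adjusted p = 3.32e-04 and 0.0158). It had adjusted p = 0.251 and 0.444 with an estimated correlation. Of 16 genes of fatty acid synthesis and handling 6 rose and 2 fell, against 6 and 4 adjusted over the list alone. After GC correction 7 rose and 0 fell, the same counts adjusted over the list alone. SCD (chromosome 10, 100347124 to 100364834) rose from 387 ± 9.84 CPM (SD, n = 3) to 509 ± 12.7 CPM (SD, n = 4), by 0.40 ± 0.04 (0.36 ± 0.03 GC-corrected), ACSL3 by 0.32 ± 0.05 (0.19 ± 0.04 GC-corrected) and the fatty acid binding protein FABP5 by 0.50 ± 0.10 (0.48 ± 0.10 GC-corrected), while the fatty acid synthase FASN turned from -0.26 ± 0.05 to 0.10 ± 0.03, past the threshold both times. This list passed only GC-corrected (camera adjusted p = 0.0238, and adjusted p = 0.255 with an estimated correlation) and not before (adjusted p = 0.238). In all 8 libraries neither list passed (camera adjusted p = 0.319 and 0.170).

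Genes of ribosomes, mitosis and DNA replication rose more often than they fell among the 7 libraries. Of 35 cytosolic ribosomal protein genes 25 rose and 0 fell, against 26 and 0 adjusted over the list alone. After GC correction 29 rose and 0 fell, against 30 and 0 adjusted over the list alone, and RPS28 rose by 0.32 ± 0.06 (0.52 ± 0.06 GC-corrected). Among 23 ribosome biogenesis genes 12 rose and 4 fell, against 14 and 4 adjusted over the list alone. After GC correction 9 rose and 0 fell, against 14 and 1 adjusted over the list alone. The nucleolar chaperone NPM1 rose from 944 ± 35.4 CPM (SD, n = 3) to 1123 ± 24.4 CPM (SD, n = 4), and NOP16, another nucleolar protein, rose by 0.39 ± 0.06 (0.47 ± 0.06 GC-corrected). Both lists passed camera's test before correction (adjusted p = 2.25e-07 and 0.00896). The pair had adjusted p = 0.455 and 0.235 with an estimated correlation. They also passed after it (adjusted p = 5.10e-07 and 0.00386). Here the pair had adjusted p = 0.703 and 0.251 with an estimated correlation. With all 8 libraries the ribosomal protein list had a median of -0.97 and passed in the opposite direction (adjusted p = 0.0233, and adjusted p = 0.721 with an estimated correlation), and the median of the biogenesis list was -0.12, which turned without TMM scaling. Of 26 genes of G2/M and mitosis 18 rose and 0 fell, against 19 and 1 adjusted over the list alone. After GC correction 16 rose and 0 fell, against 19 and 0 adjusted over the list alone. TTK and CDK1, kinases of mitosis, rose by 0.35 ± 0.06 (0.24 ± 0.05 GC-corrected) and 0.25 ± 0.04 (0.11 ± 0.04 GC-corrected). That list passed in all 8 libraries and in 7 (camera adjusted p = 0.0420 and 3.75e-07). It had adjusted p = 0.286 and 0.131 with an estimated correlation and missed the threshold GC-corrected (adjusted p = 0.0948). Of 25 genes of G1/S and DNA replication 7 rose and 2 fell, against 9 and 3 adjusted over the list alone. After GC correction 8 rose and 0 fell, against 12 and 1 adjusted over the list alone (camera adjusted p = 0.0122 and 3.32e-04, and adjusted p = 0.455 and 0.251 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose by 0.38 ± 0.05 (0.33 ± 0.04 GC-corrected), and the helicase subunit MCM2 fell by 0.25 ± 0.05 before correction and stood at -0.09 ± 0.04 after it. Of 11 replication-dependent histone genes 0 rose and 1 fell, against 0 and 0 adjusted over the list alone (GC-corrected, 1 rose and 0 fell, the same counts adjusted over the list alone). Camera's test gave adjusted p = 0.394, and 0.230 GC-corrected, past the threshold neither time. The one that fell before correction was HIST1H2BK, at -0.15 ± 0.06 and 0.08 ± 0.05 GC-corrected.

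Respiratory chain genes rose more often than they fell among the 7 libraries. Of 13 mitochondria-encoded genes of the respiratory chain 12 rose and 0 fell, against 13 and 0 adjusted over the list alone. After GC correction 10 rose and 0 fell, against 11 and 0 adjusted over the list alone. MT-ND1, a subunit of complex I, rose from 1691 ± 305 CPM (SD, n = 3) to 2397 ± 134 CPM (SD, n = 4), by 0.50 ± 0.07 (0.48 ± 0.06 GC-corrected), and MT-CO3, a subunit of cytochrome oxidase, by 0.39 ± 0.05 (0.34 ± 0.04 GC-corrected). Mitochondria-encoded genes took 3.99 ± 0.438% (SD, n = 3) of counts with vehicle and 4.83 ± 0.121% (SD, n = 4) with c-di-GMP (exact permutation test, two-sided, p = 0.0286, the smallest that 35 assignments allow, and 0.0571 after Benjamini-Hochberg adjustment over 6 measures, so that it failed the correction). The share of genes of at most 2541 bases moved in the same direction, from 14.3 ± 0.577% to 15.4 ± 0.135%, with the same exact and adjusted p. Of 29 nuclear-encoded respiratory chain genes, many of them short, 14 rose and 0 fell, against 17 and 0 adjusted over the list alone. After GC correction 15 rose and 0 fell, against 17 and 0 adjusted over the list alone, with COX6A1, a subunit of cytochrome oxidase, up by 0.41 ± 0.07 (0.30 ± 0.06 GC-corrected). The mitochondria-encoded and nuclear-encoded lists passed camera's test in 7 libraries (adjusted p = 1.31e-05 and 1.26e-04) and GC-corrected (adjusted p = 0.0205 and 0.0236). With an estimated correlation both had adjusted p = 0.455 before correction and adjusted p = 0.703 after it. With a length trend taken out as well as GC, both missed the threshold (camera adjusted p = 0.519 and 0.216), and 6 and 4 members rose and 0 fell. Over all 8 libraries the mitochondria-encoded list passed (median 0.61, adjusted p = 9.94e-05, and adjusted p = 0.422 with an estimated correlation), while the nuclear-encoded list had a median of the opposite sign, -1.13 (adjusted p = 0.0980).

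**Figure D4:**
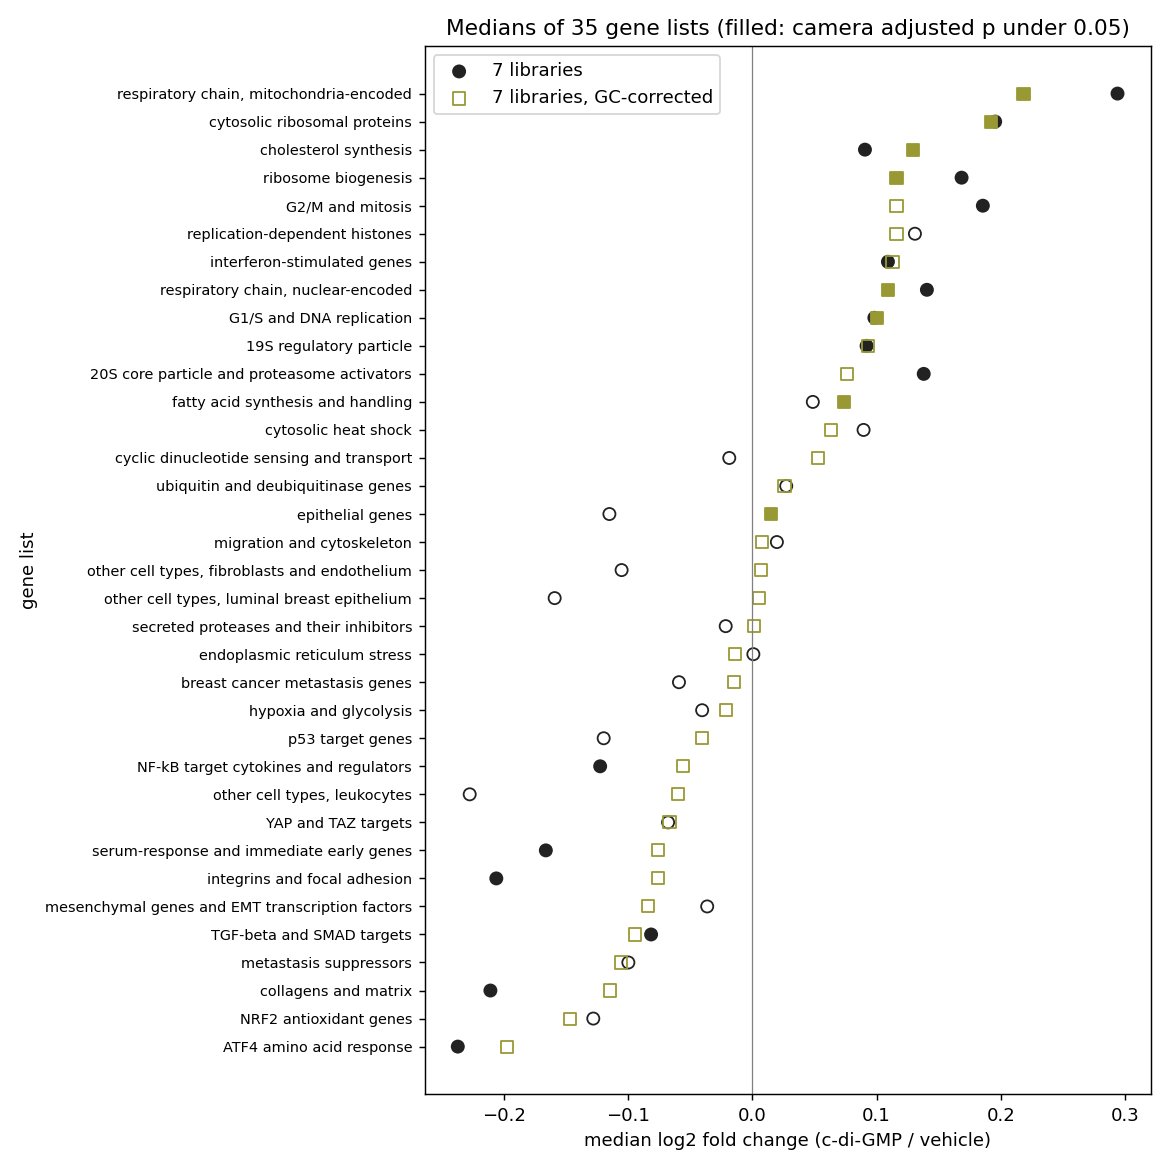
Each line of the plot is 1 of the 35 gene lists, and the points give the median log2 fold change (c-di-GMP over vehicle) of its members in the 7 libraries without vehicle replicate 3, before (circles) and after (squares) GC correction. Filled points passed camera's test at the preset correlation, 16 lists before and 8 after correction.

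Markers of other cell types were tested because cells of another kind would bring them along. Of the 4 tested leukocyte markers 0 rose and 0 fell, the same counts adjusted over the list alone (GC-corrected, 0 rose and 0 fell, the same counts adjusted over the list alone), and LAPTM5, the most abundant of them, was measured at 83.5 ± 2.64 CPM (SD, n = 3) and 81.9 ± 1.19 CPM (SD, n = 4). Of 10 luminal breast epithelium markers 2 rose and 5 fell, against 3 and 5 adjusted over the list alone. After GC correction 3 rose and 4 fell, against 4 and 4 adjusted over the list alone, and the transcription factor GATA3 fell by 0.41 ± 0.09 and by 0.33 ± 0.09 GC-corrected. Of 5 fibroblast and endothelial markers 0 rose and 1 fell, against 0 and 2 adjusted over the list alone (GC-corrected, 0 rose and 0 fell, the same counts adjusted over the list alone), and the one that fell was PDGFRB, a growth factor receptor, at -0.33 ± 0.11 and -0.18 ± 0.10 GC-corrected. The markers KRT8, KRT18 and KRT19 also stand in the epithelial list, XBP1 in that of endoplasmic reticulum stress, and COL1A1 and COL1A2 in that of collagens. None of the 3 lists of other cell types passed camera's test in 7 libraries (adjusted p = 0.394, 0.238 and 0.585) or GC-corrected (adjusted p = 0.987, 0.235 and 0.783). Across all 8 libraries 7 of the 35 lists passed. On the higher side these were G2/M and mitosis and the mitochondria-encoded genes, and on the lower side the ATF4, NF-kB and ribosomal protein lists, the metastasis suppressors (adjusted p = 0.0420, and adjusted p = 0.422 with an estimated correlation) and the luminal markers (adjusted p = 0.0105, and adjusted p = 0.432 with an estimated correlation). The signs of median, mean and test differed in 7 libraries for the lists of cyclic dinucleotide sensing, mesenchymal genes, and migration and cytoskeleton. In all 8 libraries they differed for interferon-stimulated genes, migration, collagens, cholesterol synthesis, fatty acids, G1/S and ribosome biogenesis. GC-corrected, they differed for the ubiquitin, endoplasmic reticulum stress, p53, mesenchymal, protease, integrin, TGF-beta, serum-response, hypoxia and fibroblast lists. Scaling all 8 libraries by their totals, without TMM, moved the median of all genes by 0.13 on the log2 scale and turned the sign of 10 of the 35 list medians, among them those of the 19S, migration and biogenesis lists, whereas among the 7 libraries no list median turned. With GC and length trends taken out of the 7 libraries, 7 lists passed, and 0 with an estimated correlation. More members then fell than rose in the ubiquitin (4 against 3), endoplasmic reticulum stress (3 against 0) and migration lists (6 against 3), unlike with the GC correction alone. Of the 16 lists past the test in 7 libraries 10 missed it GC-corrected, some of them with little change in their log2 fold changes, so that a lost call alone does not show that GC content carried a shift. The values were, for interferon-stimulated genes, median 0.11 before and 0.11 after, mean 0.09 and 0.08, for the 19S list median 0.09 before and 0.09 after, mean 0.09 and 0.08, for the 20S list median 0.14 before and 0.08 after, mean 0.10 and 0.08 and for the ATF4 list median -0.24 before and -0.20 after, mean -0.28 and -0.19. For TGF-beta targets they were median -0.08 before and -0.09 after, mean -0.15 and -0.06, for NF-kB targets median -0.12 before and -0.06 after, mean -0.12 and -0.10 and for G2/M genes median 0.19 before and 0.12 after, mean 0.16 and 0.12. For the collagens they were median -0.21 before and -0.11 after, mean -0.12 and -0.01, for the integrins median -0.21 before and -0.08 after, mean -0.14 and -0.06 and for serum-response genes median -0.17 before and -0.08 after, mean -0.19 and -0.09. The count of 8 lists past the test GC-corrected dropped to 5 without vehicle replicate 4 and to 5 without c-di-GMP replicate 2. With an estimated correlation 0 of the 35 lists passed in any of the 3 fits, while the test by fry, which asks whether a list's genes move one way on balance, called 2 lists in all 8 libraries, 26 in 7 and 14 GC-corrected.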

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

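The tests on GC content, on gene length, on luminal markers, on counting or scaling and on the 7 libraries in this part were chosen only after the results were seen. Vehicle replicate 3 lay far from the other 3 vehicle libraries in 15918 genes detected, in 8.08% of counts from the 10 most abundant genes, in 28.4% from genes of at most 2541 bases and 18.97% from genes of at least 6964 bases, and in 0.883% from processed pseudogenes. It lay as far in counts that made up 145.6% of the FPKM denominator, in an FPKM sum of 539972, in TBK1 at 12.87 CPM and in IRF3 at 210.45 CPM. Chance puts about 1 in 20 such groups past the limit, and all of these are the same library. The measures are not independent of each other, since shares of counts and FPKM sums both depend on which genes the counts fell on. That limit is on the gap to the nearest library of the same group, over the range of the group. Vehicle replicate 3 also passed it in 42.6% of 15415 genes, against 0.149% to 1.38% for each other library within its own group.

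For vehicle replicate 3, RNA of a cell type with abundant transcripts of its own is argued against by 0 genes that were under 1 CPM in each of the other 7 libraries and reached 20 CPM in it. RNA of a similar epithelial type stays open, because 8 of 10 luminal markers lay above the range of the other 7 libraries, such as KRT19 at 1416.0 CPM against 300.04 to 389.98 CPM and AGR2 at 110.23 CPM against 13.72 to 19.69 CPM, while ERBB2 lay below it (71.07 CPM against 82.48 to 109.22 CPM). These markers cannot decide it, since mesenchymal genes also lay apart in this library. On the scale of all 8, VIM stood at 2197.81 CPM and S100A4 at 4548.93 CPM. The other libraries held at most 811.28 and 418.06 CPM on the scale of the 7. ITGA5 and LOXL2 were lower instead, at 105.31 and 86.36 CPM against at least 238.87 and 612.61 CPM on these scales. A bias towards short transcripts may contribute, since its deviation fell with gene length across protein-coding genes (Spearman rho = -0.413), although length and GC content together explain only 18.7% of the variance of its deviation. Its counts stood at 145.6% of the FPKM denominator, against 92.4% to 94.4%. Counts, gene lengths and FPKM gave the same denominator for all shared genes with over 50 counts (relative range 3.2e-09). A different scaling by the authors is thus argued against, because a single factor cannot change the shares of counts in which this library stood apart. The TMM factor of this library was 0.664, against 1.05 to 1.07 for the others. If the authors' denominators were scaled for composition in this way, the 145.6% would follow from the odd shares of counts themselves. The percentage therefore does not show whether the authors' counting of this library differed, which stays open. Apart from RNA of other cells, no biological explanation was tested, since the labels set this library apart in no way.

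GC-rich genes were lower with c-di-GMP among the 7 libraries. The fitted GC trend did not account for all of the calls, because 33.4% of them were kept in the same direction after it was taken out. That trend used the GC content of the longest transcript, not of the expressed one. A GC bias as the whole cause of the calls therefore stays open. A GC bias that varies from library to library and an effect of c-di-GMP on GC-rich transcripts cannot be told apart. The range of slopes within the vehicle group was 69.4% of the difference between the groups, but 16.7% without vehicle replicate 1, and the slopes of the 2 groups did not overlap (exact permutation test, two-sided, p = 0.0286, the smallest that 35 assignments allow).

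Genes of ribosomal proteins and of the respiratory chain rose more often than they fell among the 7 libraries, where the share of short genes was higher with c-di-GMP. Of the cytosolic ribosomal proteins 22 still rose after GC and length trends were taken out, against 29 after GC correction alone. Their median log2 fold change went from 0.19 to 0.13, so that a trend on gene length did not account for all of these rises. The trend used the length listed for the gene and not that of the expressed transcript, so that a length bias as the whole cause stays open. Their list passed camera's test at the preset correlation (adjusted p = 3.34e-05) but not with an estimated correlation (adjusted p = 0.631), which it had missed before as well (adjusted p = 0.703). For nuclear-encoded respiratory chain genes a gene length bias may account for the call, which ended with that correction (camera adjusted p = 0.216), the median log2 fold change going from 0.11 to 0.07. For mitochondria-encoded genes the list call ended too (adjusted p = 0.519, median 0.22 before and 0.09 after), but 6 members still rose, against 10 before, which keeps it open. An effect of c-di-GMP stays open for all 3 groups.

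Other splits of the libraries were tried for each count. With all 8 libraries the real count of genes was 0, which all 35 splits reach whatever the data (highest other 0), so that this count says nothing about chance. Chance cannot be excluded there for the lists, where 20 splits gave at least the real 7 and the highest other was 10. Among the 7 libraries no other of the 35 splits gave as many as the real 4633 genes, and the highest other gave 1. Every other split mixes c-di-GMP with vehicle libraries, so that a group difference itself widens the spread and lowers its count. With 35 splits, of libraries chosen after seeing the data, the real grouping stands alone but chance is not excluded. For the 16 lists no other split gave as many either, but the highest other gave 14, as did leaving out vehicle replicate 2. GC-corrected, no other split gave as many as the 2378 genes, and the split that put c-di-GMP replicate 2 with the vehicles gave 811. Chance cannot be excluded for the 8 lists GC-corrected, where 3 splits gave as many and the highest other gave 9. None of these counts excludes a technical difference that follows the groups.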

How the results depend on the processing

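The settings with 7 libraries, the GC correction and the library quality weights were chosen after seeing the data, and the rest were planned. With all 8 libraries, where edgeR called 0 genes, 0 were also called by limma-voom and under the other scalings and filters, with FPKM and with a replicate block. DESeq2 called 106 genes (28 higher, 78 lower, 3 at least 2-fold), limma-voom with library quality weights 5430 genes (2631 higher, 2799 lower, 67 at least 2-fold), with vehicle replicate 3 weighted 0.00874, and edgeR without vehicle replicate 3 4633 genes (2106 higher, 2527 lower, 56 at least 2-fold), while edgeR without any other single library called 0. The range over each library left out was -0.014 to 0.14 for the PSMD3 log2 fold change, -0.049 to 0.19 for STING1 and 5 to 16 for the gene lists, with the lowest fold changes and the most lists without vehicle replicate 3. Among the 7 libraries the count of changed genes stayed within 1.5 times under the count-based and FPKM alternatives without GC correction, with a range over each further library left out of 3440 to 4826 (1354 to 2169 higher, 1889 to 2657 lower, 48 to 83 at least 2-fold), of which the lowest count of higher genes was without c-di-GMP replicate 4. The count of 2-fold changes was 7 with DESeq2, 24 with a stricter filter, 23 with protein-coding genes only, where fewer genes were tested, 8 with log2(FPKM + 1) and 12 with a mean FPKM of at least 1. The count of lower genes was 1616 with log2(FPKM + 1) and 1612 with log2(FPKM + 0.1), and PSMD3 changed sign in the 3 FPKM fits (0.0042, 0.0042 and 0.0042). GC correction gave 2378 genes (1342 higher, 1036 lower, 31 at least 2-fold), with a range over each further library left out of 1476 to 2638 (866 to 1456 higher, 610 to 1182 lower, 19 to 42 at least 2-fold) and the lowest counts without vehicle replicate 1. With a replicate block added it gave 1599 genes (918 higher, 681 lower, 26 at least 2-fold). Log2 fold changes that turned from negative to positive with GC correction were PSMD3 0.046, STING1 0.085, IRF3 0.039, LRRC8A 0.011, ADRM1 0.12, STUB1 0.056, HSPB1 0.063, PKP3 0.015, KRT19 0.026, KRT7 0.13, FASN 0.10, HIST1H2BK 0.081, COL1A1 0.033, and with the block added PSMD3 0.046, STING1 0.096, IRF3 0.037, LRRC8A 0.0028, ADRM1 0.10, STUB1 0.044, HSPB1 0.048, PKP3 0.023, KRT19 0.023, KRT7 0.12, FASN 0.11, HIST1H2BK 0.083, CORO1A 0.12, COL1A1 0.026. Without vehicle replicate 1 as well, PSMD3, STING1 and COL1A2 turned, and their ranges over each further library left out were -0.033 to 0.017, -0.096 to 0.040 and -0.25 to 0.11. The gene lists past the test were 0 with an estimated correlation, 2 by fry in one direction, 0 in either direction and 12 with the block in all 8 libraries. Among the 7 they were 0, 26 and 34 by the first 3 of these, GC-corrected 0, 14 and 34, and over each library left out 14 to 16 and 5 to 8 GC-corrected. From the named genes 2 were left out here on request, after the results were known. Of 196 named genes 179 passed the threshold among the 7 libraries, and of these 94 kept direction and threshold under each setting in which they were tested (16 to 20 settings, without the GC and length correction, which was not tabulated by gene), 75 missed the threshold under at least 1 and turned under none, and 10 turned under at least 1. Apart from the tests on fewer genes or libraries, the cause was not tested. The labels do not say what libraries of the same replicate number share. Their deviations from the group means correlated, for numbers 1 to 4 in all 8 libraries, at -3.41e-04, 0.184, 0.123 and -0.058, with numbers 2 and 3 but not 1 and 4 correlating best with their own, and for numbers 1, 2 and 4 in the 7 libraries at 0.015, -0.0088 and 0.0055, so that the numbers were not taken to pair the libraries.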

Other observations

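The 15 gene families in this part were chosen only after the data were seen, the target list for the hypothesis was written after CYP1A1 and CYP1B1 had been seen to fall, and values are GC-corrected among the 7 libraries. Of 78 genes of the mitochondrial ribosome, which translates mitochondria-encoded transcripts, 31 rose and 0 fell (camera adjusted p = 3.72e-04, and adjusted p = 0.504 with an estimated correlation). Among 10 S100 genes, which encode small calcium-binding proteins, 7 rose and 0 fell (adjusted p = 9.56e-05, and adjusted p = 0.382 with an estimated correlation). Of 11 tubulin genes 5 rose and 0 fell (adjusted p = 6.39e-05, and adjusted p = 0.365 with an estimated correlation), against 1 before GC correction. Of 5 metallothioneins, which bind metal ions, 2 rose and 0 fell (adjusted p = 0.0448, and adjusted p = 0.382 with an estimated correlation), and of 19 small nucleolar RNA host genes 7 rose and 0 fell (adjusted p = 0.0188, and adjusted p = 0.504 with an estimated correlation). Zinc finger genes of the ZNF series were lower as a set: of 461 tested, 4 rose and 20 fell (adjusted p = 0.00324, and adjusted p = 0.224 with an estimated correlation), and before the correction 28 rose and 55 fell. Over all 15647 genes 1342 rose and 1036 fell GC-corrected, larger shares both ways, so that falls were not more frequent in this family. The other 9 families did not pass. Over all 8 libraries the median log2 fold changes had the opposite sign for the mitochondrial ribosome (-0.49), S100 genes (-1.02), metallothioneins (-1.45) and small nucleolar RNA host genes (-0.28). For zinc finger genes the sign turned with the GC correction instead, from a median of 0.02 to -0.04 in the 7 libraries, and it was 0.04 uncorrected in all 8.

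As a hypothesis, the falls of CYP1A1 and CYP1B1 may reflect less activity of the aryl hydrocarbon receptor. The test took the median log2 fold change of 10 other known targets, of which 6 could be tested, with a bound of -0.2. The median was -0.20 (unrounded -0.204), only just past the bound, with 3 targets that fell and 0 that rose and a range from -0.83 to 0.01. Before GC correction the median was -0.12, which would not have passed. AHRR fell by 0.83, TIPARP by 0.24 and NQO1 by 0.15 on the log2 scale. NQO1 and EREG (-0.17, not past the threshold) were in gene lists already inspected, so that the test was not fully independent. The result fits the hypothesis weakly, and receptor activity itself was not measured.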
